A study of Capsicum annuum with 12 samples.

How the data were processed

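The samples are chromatin immunoprecipitation sequencing libraries from young leaves of the pepper Capsicum annuum, cultivar 59. Per the labels' protocols, ground leaf was cross-linked with 1% formaldehyde for 10 min. Chromatin was sonicated and precipitated with antibodies against H3K4me3 (ab8580), H3K27me3 or H3K9me2 (ab1220). Libraries were made with a NEBNext Ultra II kit and read as 150 bp pairs on a NovaSeq 6000. The labels list 12 samples, which are 2 immunoprecipitated replicates of each of the 3 marks and 6 input samples. Groups and replicate numbers were taken from the sample titles. The prefix YZ in the titles is not explained there.

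Each of the 6 immunoprecipitated libraries has its own peak list, so peaks were called per library and not on pooled replicates. The names of the lists say that an input served as the control, and the inputs enter the values only through that calling. No separate values of the inputs were analysed here. Per the submitters' processing notes, the tools were Trimmomatic 0.38, BWA 0.7.17, MACS2 2.2.7.1 and deepTools 3.3.0, whose roles and settings are not given in the sources used here. In each deposited list, the authors' caller gives every peak a start, an end, a summit, a fold enrichment, which is a linear ratio over the local background, and the −log10 of a p-value and of a q-value. The lowest −log10 q in the lists lay between 2.01 and 2.02, just above the value that a q of 0.01 gives. Fold enrichment and q are thus the authors' values for single peaks. They were used to describe, rank and filter peaks within a list, and their medians were compared between lists only as 1 value per library.

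The lists use sequence names with the prefix Ca_59Chr for 12 chromosomes, and names with the prefix HiC_scaffold for further sequences. The gene table at hand is of the assembly UCD10Xv1.1, which is another build. No gene was therefore assigned to a peak, and neither the planned count of genes per mark nor the planned test of gene lists was made. Positions are given as in the lists, counted from 1. Chromosome lengths of the build were not used here, and the last peak end over the 6 lists stood for the length of each chromosome, 3066 Mb in all.

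The total number of reads per library is not given in the sources used here. Depth at single peaks was recovered from the values. When the fold was read as (n + 1) over (background + 1) and p as the Poisson chance of more than n fragments, n came out within 0.01 of a whole number for 100% of the peaks of each list. This n is taken as the number of fragments over the summit. Confidence intervals of shares are Wilson intervals at 95%. They cover counting error only, since fragments and neighbouring peaks are not independent.

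Peaks that overlapped or touched were merged. Bases covered in both replicates of a mark are called shared bases, and the intervals of at least 100 bp that they form are called shared regions. A peak counted as found in the other replicate when an overlap reached 50% of the shorter peak. Overlap of replicates and of marks was compared with 1000 random circular shifts of a list within its chromosomes. The smallest p they can give is 0.001 in a one-sided and 0.002 in a two-sided test. The distal part of a chromosome was its outer 15% at each end. Differences between marks in the distal share, and in the fold of co-marked and other peaks, were tested by exact two-sided sign flips over the 12 chromosomes, or over those with at least 5 peaks of each kind when there were at least 6. Spearman and Pearson correlations over bins of 1 Mb were compared with 1000 circular shifts of the bins. Density is the share of a mark's shared bases on a chromosome over the chromosome's share of the span. The p-values were adjusted by the Benjamini-Hochberg method over the 3 pairs of marks, or over the ordered pairs that could be tested, with a threshold of 0.05. Chromosomes and bins are parts of one genome and not biological replicates. Values per library were compared by exact permutation of the mark labels over the 6 libraries.

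These tests, their alternatives and the rule for naming regions were fixed before the data were examined. Named are, for each mark, the 5 shared regions of highest mean fold and the 3 longest, for each pair of marks the 3 longest intervals they share, and for each mark the 2 densest and the 2 least dense chromosomes. The alternatives were stricter limits (−log10 q of at least 5 or 10, fold of at least 3), joining of peaks within 1 or 3 kb, other overlap rules, local shifts by 20 kb to 1 Mb, other distal widths (10% or 25%), other bins (0.5 or 5 Mb), bases found in either replicate, width matching, the replicate number as a block, and leaving out either replicate. A limit on local background, at most 5 times the lowest of the library, was added after seeing the data.

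Computations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Plots were drawn with matplotlib 3.10.9. The statistics below were tested on simulated data. With H3K4me3 moved at random, 4% of 100 simulations gave p under 0.05 for its overlap with H3K27me3. The values were 5% for H3K4me3 with H3K9me2 and 6% for H3K27me3 with H3K9me2. In the same order, 400 simulations of the bin correlation gave 3.75%, 4.5% and 7%. When 8% of H3K27me3 regions were placed on H3K4me3 regions, 20 simulations gave a mean of 6.79 times the overlap of the shifts, against 6.76 from the product of the coverages. With 40% of an H3K9me2 list of 18430 merged peaks kept in place, 39.8% were found again. The sign-flip test gave p under 0.05 in 4.3% of 1000 simulations with no difference and in 87.1% with a difference of 1 SD. When the fold was multiplied by 0.5 at co-marked H3K4me3 peaks, a difference of −12.1 was found, against −12.3 planted. Fragment numbers of 20000 simulated peaks were recovered within 0.01 in 100% of cases. For the closing tests, H3K9me2 moved at random gave p under 0.05 for its distance to H3K4me3 in 0% of 100 simulations, and all 485 regions placed at 1 to 20 kb were counted there. Peaks planted within 5 kb of the other list (29.6%) and peaks planted with a neighbour within 3 kb (67.7%) were found at the planted shares. An H3K27me3 share planted by q at 35.6% was found at 34.7% when weighted to H3K9me2.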

Results

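Chromatin immunoprecipitation sequencing measured 3 histone marks in young pepper leaves, within a study of how the pepper genome is folded. H3K4me3, trimethylation of lysine 4 of histone H3, is known from the start of transcribed genes. H3K27me3 is known from genes silenced by Polycomb proteins, and H3K9me2 from silent transposons and other repeats. Each mark had 2 replicate libraries, each with its own peak list. The labels do not say whether the replicates came from separate plants, so p-values from permuting libraries measure only the spread between these samples, which may be technical. The p-values of shifts and sign flips measure arrangement along this genome and say nothing of the spread between plants. No row of a list recurred in the other replicate of the mark.

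The H3K9me2 lists held fewer peaks than the others, while the number of H3K4me3 and H3K27me3 peaks overlapped between libraries. Covered length, width and fold were highest in both H3K4me3 libraries and lowest in both H3K9me2 libraries. H3K4me3 gave 34248 ± 396 peaks (mean ± SD, n = 2), H3K27me3 35746.5 ± 3437 and H3K9me2 17163.5 ± 2906. H3K4me3 peaks covered 31.1 ± 0.0575 Mb, H3K27me3 peaks 23.8 ± 2.39 Mb and H3K9me2 peaks 6.10 ± 1.02 Mb. The median peak was 826 ± 16.97 bp wide for H3K4me3, 461.5 ± 2.12 bp for H3K27me3 and 299.5 ± 2.12 bp for H3K9me2. The authors' median fold enrichment was 24.5 ± 0.505, 8.20 ± 0.176 and 4.29 ± 0.0309 in the same order. The replicates of a mark lay closer to each other than to those of any other mark in covered length, width and fold. An exact permutation test over the 6 libraries gave p = 0.0667 for these 3 measures, the smallest p that 90 arrangements allow, and p = 0.2 for peak number. No pair of marks could pass the threshold, as the smallest exact p of 2 against 2 libraries is 0.333. The number of H3K27me3 peaks depended on how neighbouring peaks were joined. Joining within 3 kb left 16244 H3K27me3 peaks of 1301.5 bp against 28265.5 H3K4me3 peaks of 960.5 bp (mean and mean median width of 2 libraries), which turned the order of both number and width.

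Depth over the summits followed the same order as fold. The median peak had 73 and 80 fragments over its summit in the 2 H3K4me3 libraries, 21 and 20 in those of H3K27me3, and 15 and 15 in those of H3K9me2. The weakest 10% of peaks rested on 11 or fewer fragments in both libraries of H3K9me2 and of H3K27me3. For H3K4me3 this bound was 14 and 16. Median −log10 q was 4.43 and 4.45 for H3K9me2 against 85.0 and 89.2 for H3K4me3. The limit of a −log10 q of at least 10 left 1314.5 H3K9me2 peaks per library on average, and one of at least 5 left 6958.5. These counts include peaks outside the chromosomes. On the chromosomes, the limit of 10 left 897 and 665 H3K9me2 peaks.

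H3K4me3 peaks were found again in the other replicate far more often than H3K9me2 peaks. Of the H3K4me3 peaks on the 12 chromosomes, 89.7% of replicate 1 and 90.9% of replicate 2 were overlapped, against 1.46% in shifted lists. For H3K27me3 the shares were 72.7% and 84.0%, against 1.11% in shifted lists. For H3K9me2 they were 20.6% (3795 of 18430 peaks) and 26.5% (3799 of 14342), against 0.230%. The one-sided permutation p was 0.001 for each mark, the smallest that the shifts can give. The base-pair Jaccard index, bases in both lists over bases in either, was 0.810 for H3K4me3, 0.649 for H3K27me3 and 0.127 for H3K9me2. In the 12 pairs of libraries of different marks it ran from 4.07e-05 to 0.0399. Shared bases came to 27.7 Mb for H3K4me3, 18.5 Mb for H3K27me3 and 1.29 Mb for H3K9me2.

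Within each mark, the share found again rose with the fragments over the summit. Among H3K9me2 peaks of 10 to 14 fragments, 6.60% of replicate 1 and 10.0% of replicate 2 were overlapped, while 85.1% and 93.7% were at 100 fragments or more. The 95% confidence intervals of the last values were 76.1 to 91.1% and 86.0 to 97.3%. At 10 to 14 fragments the shares were 39.1% and 59.8% for H3K27me3 and 39.9% and 39.5% for H3K4me3, so peaks of like depth were found again less often for H3K9me2. The rise of H3K9me2 was mixed with local background, the level the caller expected at the peak: 85 of the 87 and 79 of the 79 peaks with at least 100 fragments had a background above 5 times the lowest of their library. Among H3K9me2 peaks below that limit, the share rose from 6.60% and 10.0% at 10 to 14 fragments to 60.9% (of 197 peaks) and 77.1% (of 144) at 30 to 49, with too few peaks beyond. H3K9me2 peaks above the limit were found again at 66.4% and 75.1%, the others at 16.0% and 20.8%. At like depth the gap was smaller: 47.3% and 53.3% against 37.1% and 45.9% at 20 to 29 fragments. At 30 to 49 fragments it was 70.5% and 82.2% against 60.9% and 77.1%. For H3K27me3, peaks above the limit were found again less often (39.4% and 77.5%) than the others (73.1% and 84.1%). For H3K4me3 they were at 95.2% and 76.5%, against 89.7% and 91.0%. Without the H3K9me2 peaks above the limit, the mean share of H3K9me2 fell from 23.5% to 17.3%, and shared bases fell from 1.29 to 0.783 Mb.

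**Figure D1:**
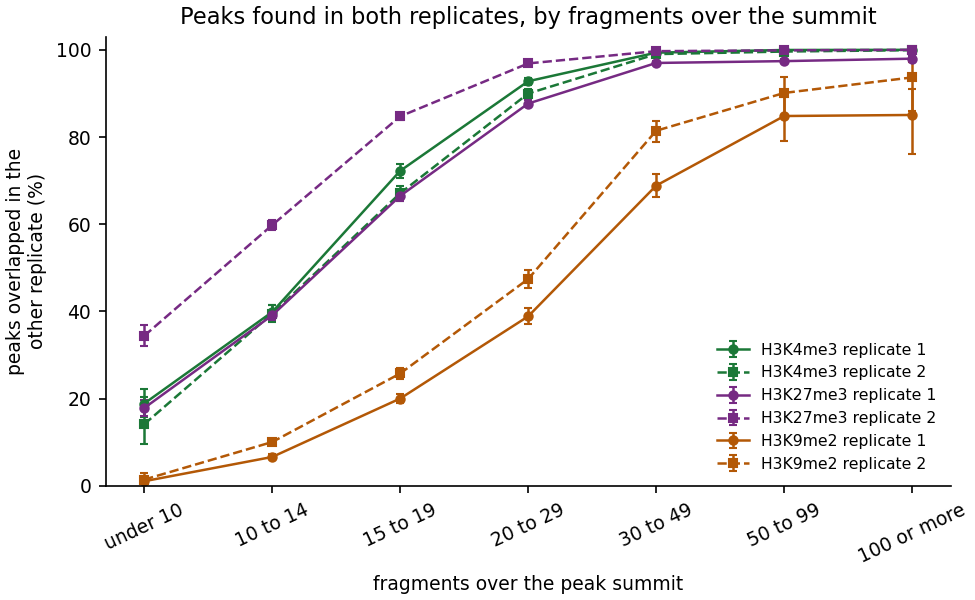
Share of peaks on the 12 chromosomes that the other replicate overlaps (vertical axis, %), by the number of fragments over the peak summit (horizontal axis), with a line per library and 95% Wilson intervals as bars. H3K9me2 libraries (orange) rise from 6.60% and 10.0% at 10 to 14 fragments to 85.1% and 93.7% at 100 or more, where 85 of 87 and 79 of 79 peaks lay at high local background.

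H3K4me3 and H3K27me3 overlapped more than chance, while H3K4me3 and H3K9me2 almost excluded each other. H3K4me3 and H3K27me3 shared 1.48 Mb in 3114 intervals of a median 391 bp, which is 5.34% of the shared H3K4me3 bases and 8.01% of the shared H3K27me3 bases. This was 8.11 times the mean of the circular shifts (two-sided permutation p = 0.002, adjusted p = 0.003). H3K4me3 and H3K9me2 shared 1 interval of 274 bases where the shifts gave a mean of 12606 bases, a ratio of 0.0217 (two-sided permutation p = 0.002, adjusted p = 0.003). H3K27me3 and H3K9me2 shared 33 intervals, 1.15 times the mean of the shifts, which did not pass the test (adjusted permutation p = 0.509). This ratio had no steady direction: it was 0.691 at a fold of at least 3, 0.672 with peaks joined within 1 kb, 0.620 with the local background limited to 5 times the lowest, and 3.48 at a −log10 q of at least 10 (adjusted permutation p = 0.0629). It passed the test only in bases of either replicate (1.23, adjusted permutation p = 0.034). Against shifts of only 20 kb to 1 Mb the ratio of H3K4me3 and H3K27me3 was 3.76, still past the threshold (adjusted permutation p = 0.003). The ratio of H3K4me3 and H3K9me2 was 0.0578 without replicate 1, and at a −log10 q of at least 10 it was 0.204 and no longer passed the test (adjusted permutation p = 0.166).

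The 3 longest intervals with both H3K4me3 and H3K27me3 lay on chromosomes 1, 8 and 10. The longest, on chromosome 1 from 29635926 to 29638527, spans 2602 bp, with a fold of 86.5 and 64.8 for H3K4me3 and of 41.7 and 24.8 for H3K27me3 in replicates 1 and 2. The next, on chromosome 8 from 97963512 to 97966070, had 24.3 and 6.91 for H3K4me3 and 28.4 and 36.5 for H3K27me3. On chromosome 10 from 244311761 to 244314244 the fold was 32.9 and 34.7 for H3K4me3 and 9.56 and 21.5 for H3K27me3. The single interval with H3K4me3 and H3K9me2 lies on chromosome 8 from 169986154 to 169986427. Of the H3K27me3 and H3K9me2 intervals, the longest lies on chromosome 9 from 128262 to 128820. The next lie on chromosome 12 from 4755634 to 4756153 and on chromosome 7 from 22729336 to 22729787. In this order, their H3K27me3 fold was 9.82 and 10.0, 7.79 and 11.4, and 2.56 and 1.75 in replicates 1 and 2. Their H3K9me2 fold was 5.73 and 6.05, 7.12 and 5.45, and 1.96 and 1.66.

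**Figure D2:**
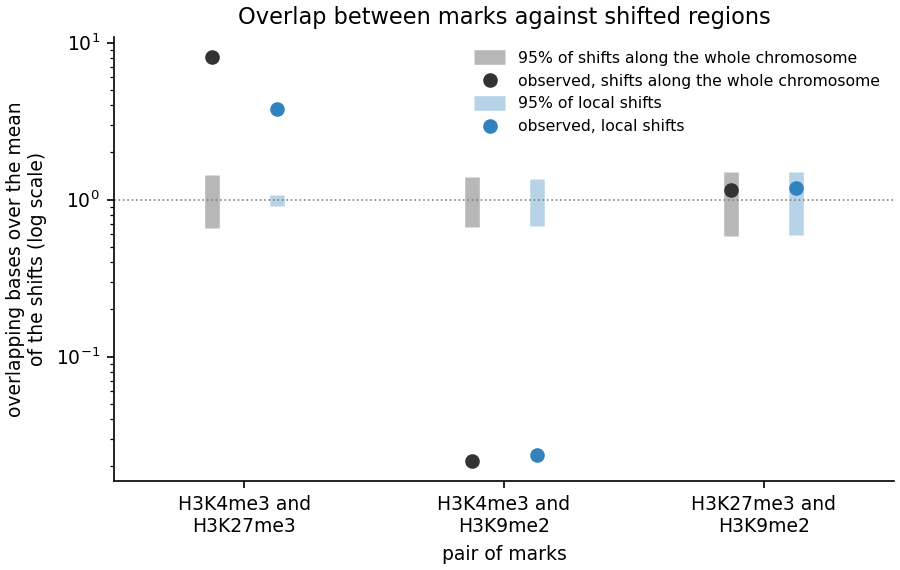
Bases shared by the marks of each pair over the mean of 1000 shifted copies (vertical axis, log scale), as points, with the central 95% of the shifts as bars. The ratio is 8.11 for H3K4me3 and H3K27me3 with shifts along the whole chromosome (dark) and 3.76 with local shifts (blue), and 0.0217 for H3K4me3 and H3K9me2.

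Where H3K4me3 and H3K27me3 met, H3K4me3 was weak for its list and H3K27me3 was strong for its list. H3K4me3 peaks with shared H3K27me3 bases made up 10.4% and 10.5% of the H3K4me3 peaks of replicates 1 and 2. Their median fold was 9.39 and 8.73, against 28.2 and 27.2 for the other H3K4me3 peaks. The mean difference over chromosomes was −18.5 ± 2.30 (SD, 12 chromosomes, co-marked peaks lower on all 12), with an adjusted exact p of 0.000732. H3K27me3 peaks with shared H3K4me3 bases were 9.73% and 10.2% of their lists. Their median fold was 10.5 and 10.5, against 8.07 and 8.18 for the others, a mean difference of 2.30 ± 0.727 (higher on 12 of 12 chromosomes, adjusted exact p = 0.000732). Most of both differences went with peak width. Co-marked H3K4me3 peaks were narrower than the others (554 against 839 bp in replicate 1) and co-marked H3K27me3 peaks wider (644 against 448 bp). Matched on width, the differences were −4.02 (adjusted exact p = 0.00146) and 0.654 (adjusted exact p = 0.00366), and that of H3K27me3 peaks covered over at least 50% was 0.262 and did not pass the test (adjusted exact p = 0.0840).

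H3K27me3 peaks that met H3K9me2 were few and, by their median fold, weak. They were 136 and 98 peaks, 0.365% and 0.296% of the lists, with a median fold of 2.86 and 3.46 against 8.25 and 8.45 for the others. The mean difference was −5.08 ± 0.759 over the 8 chromosomes with enough peaks, lower on each of them (adjusted exact p = 0.00781), and −3.29 when matched on width. With the local background of both marks limited to 5 times the lowest, 22 and 30 such peaks were left, with a median fold of 4.09 and 4.14 against 8.25 and 8.46, and no chromosome had enough for the test. The H3K27me3 peaks above that limit, with or without H3K9me2, had a median fold of 3.44 and 3.81. The reverse, H3K9me2 peaks that met H3K27me3, came to 52 and 49 peaks and could be compared on 4 chromosomes only, too few for the test. In single replicates their fold differed by −0.274 without replicate 1 (153 peaks, higher on 3 of 12 chromosomes, adjusted exact p = 0.0342) and by −0.138 without replicate 2 (220 peaks, higher on 5 of 12, adjusted exact p = 0.503). H3K4me3 peaks that met H3K9me2 numbered 3 and 7, and H3K9me2 peaks that met H3K4me3 numbered 4 and 2.

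H3K4me3 and H3K27me3 lay mostly toward the chromosome ends, and H3K9me2 less so. The outer 30% of a chromosome's span held 61.8% ± 6.17 of its shared H3K4me3 bases (SD, 12 chromosomes), 66.7% ± 8.78 of its H3K27me3 bases and 46.2% ± 13.5 of its H3K9me2 bases. H3K27me3 was the more distal of the first pair on 9 of 12 chromosomes, with a mean difference of H3K4me3 minus H3K27me3 of −4.83 points (adjusted exact p = 0.0264). In the outer 10% at each end this difference was −3.63 points and did not pass the test (adjusted exact p = 0.0586). H3K4me3 exceeded H3K9me2 by 15.6 points on average (higher on 10 of 12 chromosomes) and H3K27me3 exceeded it by 20.4 points (11 of 12), both with an adjusted exact p of 0.00293. The H3K4me3 share ranged from 46.2% on chromosome 1 to 73.0% on chromosome 3, and the H3K9me2 share from 27.5% on chromosome 3 to 67.8% on chromosome 5. The middle 40% of the span held 15.8% of shared H3K4me3 bases, 10.7% of H3K27me3 and 31.8% of H3K9me2. In the single H3K9me2 libraries the distal share was lower than in shared bases, at 36.8% and 39.1%, so that H3K4me3 exceeded H3K9me2 by 25.5 points without replicate 2. At a −log10 q of at least 10, none of the 3 differences passed the test: H3K4me3 minus H3K27me3 was −5.08 points (exact p = 0.0210, adjusted 0.0630), H3K4me3 minus H3K9me2 8.23 (adjusted exact p = 0.383) and H3K27me3 minus H3K9me2 13.3 (adjusted exact p = 0.240).

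**Figure D3:**
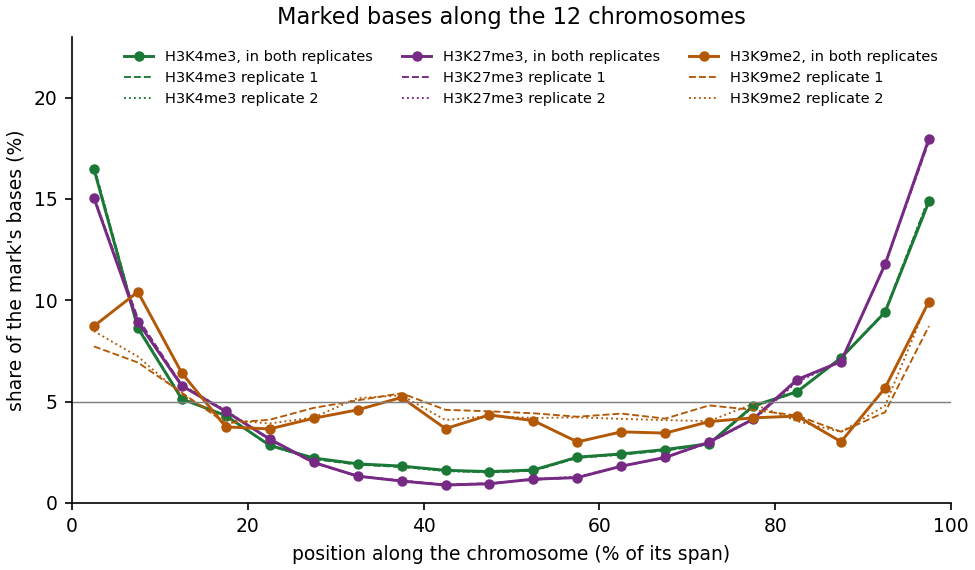
Share of each mark's bases (vertical axis, %) in 20 equal segments along the chromosome (horizontal axis, % of its span), summed over the 12 chromosomes, for shared bases (points) and each replicate (dashed and dotted lines); the grey line at 5% is an even spread. The first and the last segment hold 16.5% and 14.9% of shared H3K4me3 bases but 8.72% and 9.93% of shared H3K9me2 bases.

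Across 3074 bins of 1 Mb, the amounts of H3K4me3 and H3K27me3 rose together, while those of H3K9me2 gave correlations near 0 with either in shared bases. Spearman's rho was 0.611 and Pearson's r 0.579 for H3K4me3 and H3K27me3 (adjusted permutation p = 0.002 and 0.00599). For H3K4me3 and H3K9me2, rho was −0.0552 (adjusted permutation p = 0.002) and r was −0.0172 (adjusted permutation p = 0.168). For H3K27me3 and H3K9me2, rho was −0.0402 (adjusted permutation p = 0.002) and r −0.00303 (adjusted permutation p = 0.346). Bins are not independent replicates. No shared base lay in 5.40% of the bins for H3K4me3, in 23.2% for H3K27me3 and in 46.3% for H3K9me2. Shared H3K9me2 bases were sparse, and rho with H3K4me3 and H3K27me3 was further from 0 in fuller sets. It was −0.147 and −0.160 without replicate 2, and −0.117 and −0.130 without replicate 1. In bases of either replicate it was −0.168 and −0.186 (adjusted permutation p = 0.002 for each of these). Pearson's r stayed near 0 in these sets and did not pass the test (adjusted permutation p of at least 0.195). It was −0.0286 and −0.00455 without replicate 2, and −0.00370 and −0.00739 without replicate 1. In bases of either replicate r was −0.0149 and −0.00618. In bins of 5 Mb rho was 0.0377 and 0.0589 and did not pass the test (adjusted permutation p = 0.581 and 0.857). At a −log10 q of at least 5 and 10, the rho of H3K27me3 and H3K9me2 was 0.000716 and 0.0164 (adjusted permutation p = 0.106 and 0.663), and at 10 that of H3K4me3 and H3K9me2 was −0.0150 (adjusted permutation p = 0.105), so these calls were lost too.

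H3K4me3 and H3K27me3 were densest on chromosome 2, and the H3K9me2 bases found in both replicates on chromosomes 1 and 2. Shared H3K4me3 bases were densest on chromosomes 2 (1.95 times the even share) and 8 (1.44) and least dense on chromosomes 9 (0.668) and 5 (0.688). H3K27me3 was densest on chromosomes 2 (1.68) and 3 (1.48) and least dense on chromosomes 9 (0.691) and 10 (0.717). For both marks the replicates differed by little, with 1.95 and 1.94 for H3K4me3 and 1.64 and 1.63 for H3K27me3 on chromosome 2. Shared H3K9me2 bases were densest on chromosomes 1 (2.02) and 2 (1.91) and least dense on chromosomes 12 (0.637) and 11 (0.651). The single libraries gave lower values, 1.28 and 1.29 on chromosome 1 and 1.24 and 1.24 on chromosome 2. The highest density over the lowest was 3.18 in shared H3K9me2 bases but 1.56 without replicate 1 and 1.497 without replicate 2, and it was 6.66 at a −log10 q of at least 5. Without peaks whose local background was above 5 times the lowest, the density was 0.676 on chromosome 1 and 0.670 on chromosome 2, which put both below an even share. Densities were described with no test.

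**Figure D4:**
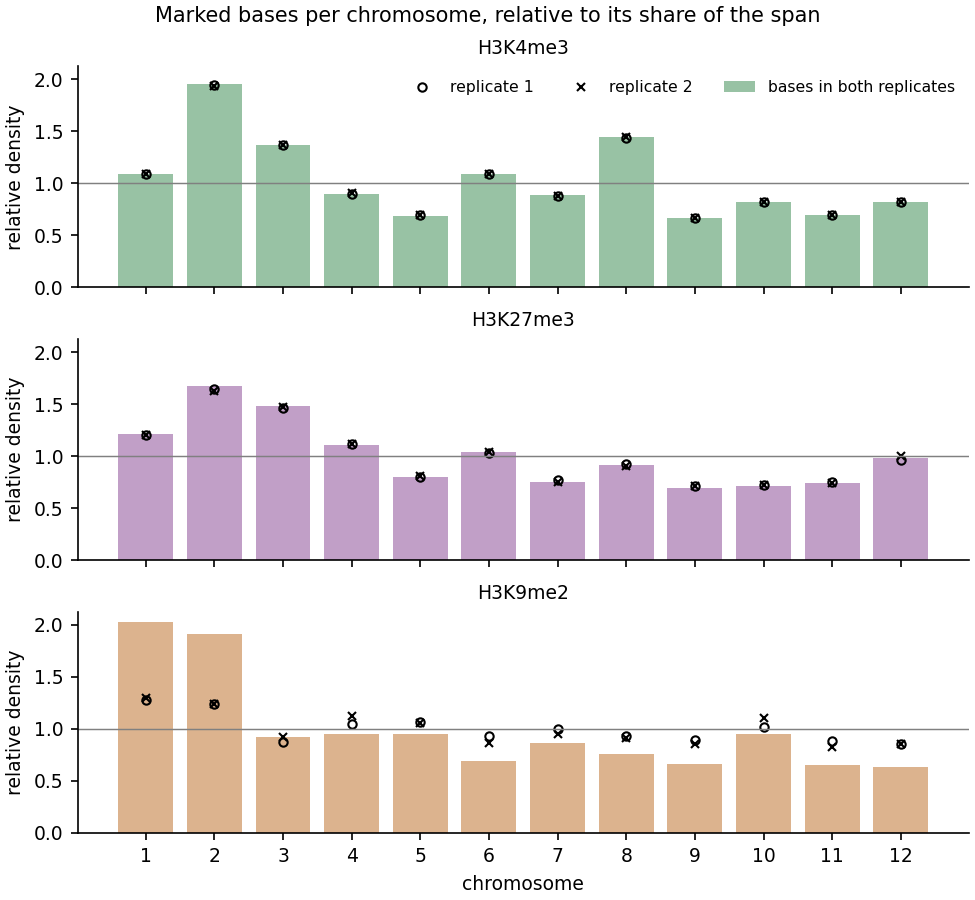
Density of each mark per chromosome (vertical axis, share of the mark's bases over the chromosome's share of the span; 1 is an even spread), for shared bases (bars) and each replicate (circles and crosses). H3K4me3 and H3K27me3 peak on chromosome 2 (1.95 and 1.68), while shared H3K9me2 bases peak on chromosomes 1 and 2 (2.02 and 1.91), where the single libraries lie near 1.28 and 1.24.

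The 5 shared H3K4me3 regions of highest mean fold lay on chromosomes 3, 6, 11, 3 and 5. That on chromosome 3 from 227531923 to 227533993 had a fold of 448 ± 6.51 (SD, n = 2), with 1754 and 2222 fragments over the summit. The others differed more between replicates. They were chromosome 6 from 240478887 to 240480026 (440 ± 312), chromosome 11 from 124648366 to 124649323 (428 ± 403), chromosome 3 from 262322316 to 262323216 (426 ± 253) and chromosome 5 from 129964773 to 129965942 (411 ± 115). The longest shared H3K4me3 regions were 7212 bp on chromosome 2 from 161562310 to 161569521, 6487 bp on chromosome 4 from 47526706 to 47533192 and 6451 bp on chromosome 3 from 256928485 to 256934935. Their mean fold was 192, 159 and 185.

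The 5 shared H3K27me3 regions of highest mean fold lay in the distal parts of chromosomes 7, 3 and 10. They were chromosome 7 from 263519488 to 263521531 (fold 144 ± 67.3, n = 2), chromosome 3 from 259932845 to 259937815 (143 ± 45.0), chromosome 3 from 21062999 to 21063665 (139 ± 73.1), chromosome 10 from 229414136 to 229415546 (138 ± 40.9) and chromosome 3 from 24485750 to 24487547 (130 ± 9.28). The longest shared region of any mark was an H3K27me3 region of 10507 bp on chromosome 1 from 314501098 to 314511604, with a mean fold of 43.3. The next H3K27me3 regions spanned 7659 bp on chromosome 4 from 55088723 to 55096381 and 7489 bp on chromosome 7 from 85787700 to 85795188.

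H3K9me2 regions stayed short and weak by comparison. The highest mean fold was 14.7 ± 0.713 (n = 2) on chromosome 8 from 111318196 to 111318913, with 84 and 116 fragments over the summit. It was 13.3 ± 0.0356 on chromosome 6 from 98532082 to 98532548 and 13.3 ± 0.193 on chromosome 5 from 132558240 to 132558868. Next came chromosome 5 from 152147755 to 152148298 (13.1 ± 5.83) and chromosome 4 from 241473682 to 241474123 (12.3 ± 3.71). The longest shared H3K9me2 regions were 2504 bp on chromosome 9 from 51127958 to 51130461, 1994 bp on chromosome 11 from 6085463 to 6087456 and 1866 bp on chromosome 10 from 51088537 to 51090402. All 3 had a local background of 22.9 to 46.8 fragments, and their mean fold was 5.10, 5.63 and 4.96. The median background over the H3K9me2 peaks was 2.62 and 2.77 in replicates 1 and 2. The 5 regions of highest mean fold also lay above it, at 2.80 to 4.97 in replicate 1 and 3.34 to 8.11 in replicate 2.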

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

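Of the tests below, those on fragments per peak, on local background and on the strongest H3K4me3 sites were chosen after the result was seen. Those on neighbouring peaks and on the strongest H3K27me3 sites were chosen before. Local shifts were fixed before the data were examined, but their reading as a test of chromosome ends was set after their result was seen.

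Peaks on sequences outside the 12 chromosomes count in the number, covered length, width and fold per library but were left out of the comparisons by position, and are given here as signal outside those comparisons. There were 61 and 113 for H3K4me3, 893 and 218 for H3K27me3, and 788 and 767 for H3K9me2 (replicates 1 and 2). A single scaffold held 561 and 547 of the H3K9me2 peaks, 540 and 79 of the H3K27me3 peaks, and 5 and 37 of the H3K4me3 peaks, all within its first 3.92 Mb.

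The pile of H3K9me2 on these sequences and on chromosomes 1 and 2 goes with loci of high local background, whose median at H3K9me2 peaks outside the chromosomes was 9.67 and 10.4 times that on the chromosomes. This ratio was 10.3 and 4.63 for H3K27me3 and 1.01 and 3.78 for H3K4me3, so high background there was not particular to H3K9me2. On chromosomes, 69.5% and 68.3% of the H3K9me2 peaks with a background above 5 times the lowest lay on chromosomes 1 and 2, which hold 16.7% of the span, against 18.1% and 25.9% of such H3K4me3 peaks and 19.3% and 27.5% of such H3K27me3 peaks. Without such peaks, the density of shared H3K9me2 bases on chromosome 1 fell to 0.676. A candidate cause is sequence with more copies in the plant than in the assembly: at such loci many fragments let a smaller enrichment pass, and the median fold there was 3.38 and 3.28 against 4.42 and 4.46 at other H3K9me2 peaks. Copy number was not measured, and a true enrichment of H3K9me2 in repeats of these sequences stays open and untested. High-background peaks of the other marks were not gathered on chromosomes 1 and 2 to that extent. Outside the chromosomes this contrast did not hold for H3K27me3 replicate 1. The single scaffold held 540 of its 893 outside peaks, against 561 of 788 for H3K9me2 replicate 1 and 79 of 218 for H3K27me3 replicate 2.

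H3K9me2 peaks were found in the other replicate at 23.5%, the mean of 2 libraries, against 78.4% for H3K27me3. Weak evidence per peak may account for part of this gap. Weighted to the −log10 q of the H3K9me2 peaks, the H3K27me3 share was 45.1% (36.8% and 53.4%), still above H3K9me2 by more than the replicates differed. Whether weak evidence explains the rest cannot be told, as the weighting matched the q of a peak but not its surroundings. More H3K27me3 than H3K9me2 peaks had a neighbour within 3 kb, which can raise overlap. Whether broad domains called as narrow pieces in different places add to it could not be told. Of the H3K9me2 peaks without a partner, 28.5% had a peak of the other replicate within 5 kb, against 5.02% and 6.47% in local shifts, short of the 50% set for a main cause. A difference between the plants or preparations of the replicates stays open, as the labels do not describe it.

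H3K4me3 and H3K27me3 overlapped 8.11 times as much as whole-chromosome shifts gave. A shared preference for chromosome ends is not the whole cause, as the ratio was 3.76 under local shifts. Unspecific recovery at the strongest H3K4me3 sites is argued against as well: of the 10% of H3K4me3 peaks with the highest fold, 3.13% and 3.51% were co-marked, against 10.4% and 10.5% of all. Recovery of strong H3K27me3 sites by the H3K4me3 antibody cannot be told apart from true co-marking. Of the top 1% of H3K27me3 peaks, 49.6% and 47.7% carried H3K4me3, against 9.73% and 10.2% of all. Their 95% intervals (44.6 to 54.7% and 42.4 to 53.1%) include the bound of 50% set for recovery. This bound is not the rule used for H3K4me3 sites, and recovery need not reach it. By that rule, the top 10% of H3K27me3 peaks (23.3% and 23.5%) exceeded all peaks, which recovery and true co-marking both allow. Both marks on the same nucleosomes, or each in different cells of the leaf, stay open and untested.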

How the results depend on the processing

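Of 111 alternative values for the 12 tested results on pairs of marks, 96 kept their direction and their side of the threshold; the alternative with the limit on local background was chosen after seeing the data. Ratios of values per library cannot pass the threshold, so 77 of their 84 values show only a kept direction. The p of the replicate overlaps was the smallest the shifts can give throughout and says nothing of their stability. Their mean shares ran from 85.1 to 94.8% for H3K4me3, from 64.5% (reciprocal overlap) to 82.4% for H3K27me3 and from 17.3% (background limit) to 31.5% (−log10 q of at least 10) for H3K9me2, against 90.3%, 78.4% and 23.5%. The 8.11-fold overlap of H3K4me3 and H3K27me3, their bin correlation and the lower fold of H3K4me3 peaks with H3K27me3 kept their calls under each alternative run. The fold of H3K27me3 peaks with H3K9me2 could not be tested with the background limit or at a −log10 q of at least 5 or 10, for lack of peaks. The alternatives for genes were not run, as no gene was assigned. The cause was not tested for the changes below, and a fall in peak number is named there as a value only.

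Peak number of H3K4me3 over H3K27me3 (0.958) turned to 1.03 and 1.26 at −log10 q of at least 5 and 10, to 1.37 and 1.74 with peaks joined within 1 and 3 kb, and was 0.904 to 1.02 with either replicate left out. The H3K9me2 lists fell from a mean of 17163.5 peaks to 6958.5 and 1314.5 at these limits, counting peaks outside the chromosomes. At a −log10 q of at least 10, 897 of 1458 and 665 of 1171 H3K9me2 peaks lay on the chromosomes. In the full lists, 18430 of 19218 and 14342 of 15109 did. Only peaks on the chromosomes enter the overlap, rho and distal values below. The H3K27me3 lists fell from 35746.5 to 22606.5 at a −log10 q of at least 10 and to 22519.5 and 16244 by joining. Joining within 3 kb also turned the ratio of covered length to 0.922 and of median width to 0.738. At a −log10 q of at least 10, with few H3K9me2 peaks left, the overlap of H3K4me3 and H3K9me2 (0.204) and their rho (−0.0150) no longer passed. Neither did the distal differences from H3K9me2 (8.23 and 13.3 points). These differences also shrank in size. The distal share of H3K9me2 was 46.2% in the full lists, 49.5% at a limit of 5 and 53.4% at 10. The distal difference of H3K4me3 and H3K27me3 (−5.08 points) kept its size, with an exact sign-flip p of 0.0210. It was lost only by the adjustment over the 3 pairs (0.0630). The overlap of H3K27me3 and H3K9me2 (1.15) was 0.691 at a fold of at least 3, 0.672 with peaks joined within 1 kb and 0.620 with the background limit. It was 1.41 and 3.48 at −log10 q of at least 5 and 10 (adjusted permutation p = 0.0629 at the latter) and passed the test only in bases of either replicate (1.23). Their rho was 0.000716 and 0.0164 at −log10 q of at least 5 and 10. In bins of 5 Mb it was 0.0589, and that of H3K4me3 and H3K9me2 0.0377. In the outer 10% the distal difference of H3K4me3 and H3K27me3 was −3.63 points and did not pass. The fold difference of H3K27me3 peaks covered by H3K4me3 over at least 50% was 0.262 and did not pass.

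Highest over lowest density was 2.90 to 2.91 for H3K4me3, 2.30 to 2.32 for H3K27me3 and 1.497 to 1.56 for H3K9me2 with either replicate left out. At −log10 q of at least 5 it was 2.45 for H3K27me3 and 6.66 for H3K9me2, and with the background limit 2.45 and 2.10.

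With the replicate number as a block, the overlaps were 8.08, 0.0419 and 1.12 times the shifts, the distal differences −4.44, 24.3 and 28.8 points, the rho over bins 0.629, −0.132 and −0.145, and no call of these changed. Deviations of same-numbered libraries over 1 Mb bins correlated at −0.0884, −0.00732 and 0.0233. Such values cannot settle whether the numbers pair the samples, as differences between called lists may hide a shared source. The labels do not say so either. Depth over the summit was lowest for H3K9me2, with a median of 15 fragments, and the depth of whole libraries is not given in the sources used here.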

Other observations

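The tests on H3K9me2 near H3K4me3, on H3K27me3 across H3K4me3 regions and on clusters were chosen after the pattern was seen, and that on the first bases of chromosomes before its result was seen.

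H3K27me3 peaks came in clusters. Of the H3K27me3 peaks of replicates 1 and 2, 77.7% and 76.3% had another peak of their list within 3 kb, against 23.1% and 21.2% when peaks were moved at random by up to 500 kb. The shares were 31.9% and 29.8% for H3K4me3 (20.1% and 19.7% when moved) and 29.99% and 29.6% for H3K9me2 (7.07% and 6.63% when moved). Joined within 3 kb, H3K27me3 formed 82 and 59 clusters of at least 20 kb, while H3K4me3 formed 0 and 0 and H3K9me2 0 and 5. The longest lay on chromosome 2 from 176182292 to 176348548 in replicate 1, where 81 peaks spanned 166 kb, and from 176233180 to 176325645 in replicate 2, where 44 peaks spanned 92.5 kb. The clustering is consistent with H3K27me3 domains that the caller broke into narrow peaks, a hypothesis that was tested here only against random placement.

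H3K9me2 kept a distance from H3K4me3. Of 4266 shared H3K9me2 intervals, 2 lay within 1 kb of the nearest shared H3K4me3 interval, where local shifts of 20 kb to 1 Mb gave a mean of 131, and 38 lay at 1 to 5 kb, where they gave 269. Over 1 to 20 kb the count was 458 against 883, a ratio of 0.519 (two-sided permutation p = 0.002, the smallest that the shifts can give). Beyond 20 kb it exceeded the shifts, with 906 against 699 at 20 to 50 kb. This suggests a zone around H3K4me3 that H3K9me2 peaks avoid, wider than the H3K4me3 peaks themselves. Low power to call H3K9me2 near open chromatin was not tested and could give the same pattern.

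At H3K4me3 regions, H3K27me3 coverage was highest at their centres. Shared H3K27me3 covered 8.37% of the positions at the midpoints of shared H3K4me3 intervals, 1.95% at 1 kb from them, 1.70% at 2 kb and 1.36% at 1 Mb. Coverage at the centre exceeded that at 2 kb on 12 of 12 chromosomes (exact sign-flip p = 0.000488, the smallest for 12 chromosomes). This follows from the overlap of the 2 marks and adds no evidence to it. Shared H3K27me3 intervals at 1 to 5 kb from the nearest H3K4me3 interval also exceeded local shifts, with 4135 against 3768 (two-sided permutation p = 0.002).

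A hypothesis that H3K27me3 marks the first 50 kb of chromosomes in general did not hold. A dense stretch at the start of chromosome 1, with 44.7% of its first 50 kb covered by shared H3K27me3, had prompted it. Coverage of the first 50 kb exceeded that of the rest of the first 1 Mb on 5 of 12 chromosomes only (means 7.69% and 1.55%, exact sign-flip p = 0.122), and the other chromosomes had no shared H3K27me3 there.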
